A study of Mus musculus with 92 samples.

How the data were processed

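Groups of the 92 libraries were taken from the sample labels alone: 15 groups in 4 cohorts, with mice of 6 weeks per the labels of the first 3 cohorts. The labels name the dorsal raphe for those cohorts and give no tissue name for the 19 libraries of the fluoxetine cohort, and they give no sex for any mouse. Per the labels, RNA of the first 3 cohorts was purified with RNeasy Micro columns and libraries were made with a TruSeq RNA v2 kit, and the fluoxetine libraries were made from total RNA.

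The deposited values of every cohort are raw counts per gene, not normalised. Per the file headers, counts of the first defeat cohort were made by the authors with featureCounts 1.6.4 over whole gene bodies, introns included and without strand, so transcripts of antisense or overlapping genes are not separated. Counts of the fluoxetine cohort were made, per the file headers, with featureCounts 2.0.1 over exons after removal of duplicate reads. Counts of the second cohort ended with closing lines for reads outside genes, which held 26.52 to 31.64% of the total and were left out. The vector cohort came as 1 table of 17024 genes (16528 with a symbol) in which genes of low counts were already left out, the lowest gene total being 377. That table held 42 columns, of which 4 matched no sample and were not used. The submitters' processing notes name FastQC 0.72, HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 2.11.40.6 with the mm10 build. The other cohorts listed 52636 genes, 52403 of them with a symbol. Gene positions are those of GRCm38.

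Total counts were 10.77 to 42.28 M per library in the first defeat cohort (median 25.94), 16.58 to 53.72 M in the second (39.2), 28.4 to 94.77 M in the vector cohort (55.06) and 8.7 to 31.16 M in the fluoxetine cohort (18.14). Genes were kept with the filterByExpr rule of edgeR, which left 17036, 18849, 17024 and 18673 genes. Cohorts were fitted apart, with all groups of a cohort in 1 model without covariates, the sequencing lane being fitted only among the other settings. TMM factors and the robust quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) gave log2 fold changes, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. There were 15 comparisons of groups, of which 2 were interactions. Each library is named by the labels as a replicate, and the p-values treat each as an independent mouse. The labels do not say whether mice shared a cage, litter or day, so p-values are too small if they did.

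Gene lists numbered 31, of which 15 mark cell types and 16 name processes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Each test was adjusted over the lists of a comparison and not over the comparisons. Members of a list were also adjusted over the list alone. That adjustment did not cover the number of lists and comparisons (442 list tests), so some members are likely to pass by chance. Cell type scores were the mean log2 CPM of a list (prior count 2), compared by exact permutation of libraries and adjusted over the cell types of a comparison. Signatures were the 200 genes of smallest p of a stress comparison. They were scored as the mean of rising minus the mean of falling genes in libraries that had not chosen them, with an exact permutation test adjusted over 8 tests.

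Comparisons, tests, lists, the first set of other settings below and the rule for named genes were fixed before the data were examined. The rule named up to 8 genes of the highest and 8 of the lowest log2 fold change among those that passed with a mean of at least 1 CPM. It also named up to 4 members of each list with the smallest p in the comparison, and always Tph2, Slc6a4, Fev, Slc18a2, Fos and Fkbp5. H3f3a, H3f3b, Xist and Y-linked transcripts were read per library as a check of labels. Named beyond this rule, after their values were seen, were Glrx5, Psrc1, Creg2 and Gm48267, which another tool or setting called. So were members of a list beyond its first 4 where they are given among those that passed over the list alone, such as Isl1 and Tmem119. Some genes that the rule named are not reported here, most of which did not pass, and they remain in the counts and tests of their lists.

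The first set of other settings was DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors in edgeR, no filter on low counts, only the libraries of the compared groups, 2 surrogate variables from sva 3.50.0, the sequencing lane, the run of accession numbers, the number in the titles as a block, signatures of 50 and 1000 genes or without cell type genes, and leaving out single libraries. Settings added after the data were seen were the level of the serotonin neuron list as a covariate, the data without libraries of low Tph2 (under 0.1 of the cohort median), the data without libraries that stood apart, and the tests of lists under alternatives. Libraries stood apart when Y-linked counts were under 0.6 of the cohort median, Pcsk1n was over 2.5 times it or Gm10800 over 100 times it.

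Whether equal numbers in the titles mark pairs was checked by correlating libraries of the same number between groups after removing group means. In the second cohort the 5 shared numbers gave correlations of -0.27 to 0.28, so its libraries were not taken as pairs. In the vector cohort 3 of 13 pairs of groups correlated, and of these only the stressed mice with the empty and the mutant vector shared 3 numbers (0.14 to 0.44), so that comparison is also given with the number as a block. The 259 pairs of libraries within groups were checked for copies of the same library, and the lowest chi-square per degree of freedom was 3.77.

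Counts simulated per cohort with 200 changed genes tested the pipeline, but not recovery in real counts. At 1.5-, 2- and 4-fold changes edgeR recovered 47.8, 68.7 and 100% in susceptible against control mice of the first cohort. It recovered 76.1, 92.5 and 97% in the second cohort and 85.1, 92.5 and 100% for stress under the empty vector. In susceptible against control mice given water it recovered 52.2, 88.1 and 93.9%. Random splits of the libraries into groups of the same sizes were refitted, 100 per comparison and 50 in the vector cohort.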

Results

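Gene expression was measured by RNA sequencing in 92 mouse brain libraries from 4 cohorts and 15 groups. The libraries of the first 3 cohorts were labelled as dorsal raphe nucleus, the main source of forebrain serotonin, and those of the fluoxetine cohort carried no tissue name. The first defeat cohort held 8 control, 8 susceptible and 8 resilient mice, sorted by their behaviour after chronic social defeat, in which a mouse is exposed repeatedly to an aggressor. The second defeat cohort held 5 control and 6 defeated mice. The vector cohort held control and stressed mice given a vector labelled GFP and described as empty (the empty vector, n = 7 and 8), a vector carrying histone H3.3 with its glutamine 5 replaced by alanine (the mutant vector, n = 7 and 6) or wild-type H3.3 (n = 2 and 8). Glutamine 5 is the residue of histone H3 to which transglutaminase 2 (Tgm2) attaches serotonin. The fluoxetine cohort held control mice given water (n = 5) or the serotonin reuptake inhibitor fluoxetine (n = 5), and susceptible mice given water (n = 5) or fluoxetine (n = 4). Values below are means ± SD in counts per mega counts (M) of the library (CPM), and log2 fold changes are the first-named group over the second with the standard error (SE) of the edgeR fit.

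Transcripts of serotonin neurons spread widely within most groups. Tph2, the enzyme that makes serotonin in neurons (chromosome 10, 115078641 to 115185022, GRCm38), ranged from 6.47 to 2220 CPM in the first defeat cohort, 1.02 to 535 CPM in the second, 1.88 to 600 CPM in the vector cohort and 1.29 to 1900 CPM in the fluoxetine cohort. Its highest value was 23.3 to 772 times the lowest within 12 of 15 groups, and 2.96 to 6.39 times in both wild-type vector groups and stressed mice with the empty vector. In the first cohort Tph2 averaged 613 ± 598 CPM in control (n = 8), 894 ± 693 CPM in susceptible (n = 8) and 1110 ± 956 CPM in resilient mice (n = 8). The serotonin transporter Slc6a4 averaged 487 ± 501, 672 ± 544 and 818 ± 715 CPM in the same groups. Libraries under 0.1 of their cohort's median Tph2 are called libraries of low Tph2 below, and numbered 6, 3, 4 and 6 in the 4 cohorts. A further 5 libraries of the first and 2 of the vector cohort stood apart by their counts of Y-linked genes, Pcsk1n or Gm10800.

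**Figure D1:**
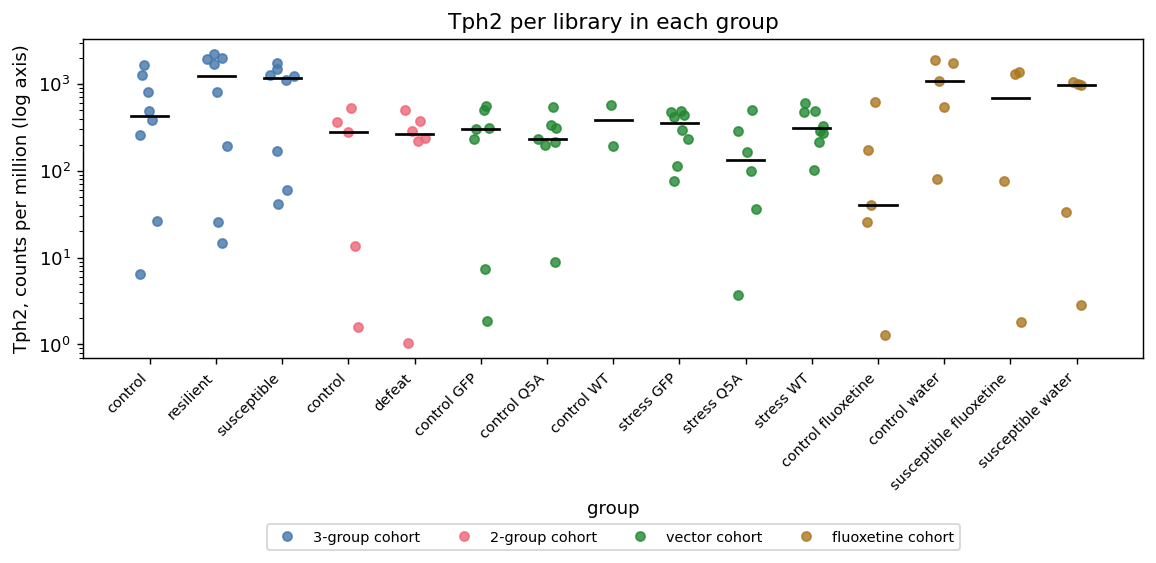
Tph2 in CPM on a log axis for each of the 92 libraries, by group and coloured by cohort, with a line at each group's median. The 8 controls of the first defeat cohort range from 6.47 to 1680 CPM.

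The first comparison asked whether expression differed in susceptible mice. The globin transcripts were higher: Hbb-bs, a beta globin (chromosome 7, 103826534 to 103828096), averaged 41.3 ± 26.5 CPM in susceptible mice (n = 8) and 16 ± 5.96 CPM in controls (n = 8), a log2 fold change of 1.37 (SE 0.37). The alpha globins Hba-a1 (16.5 ± 12.2 against 6.36 ± 3.02 CPM) and Hba-a2 (10.6 ± 7.94 against 4.15 ± 1.91 CPM) had log2 fold changes of 1.37 and 1.35, and reads are shared between these near-identical genes. These 3 of the 5 blood cell genes passed when adjusted over the list alone (edgeR adjusted p = 0.00582 for Hbb-bs), 0 passed over all genes, and the 3 still passed when any single library was left out. The mean blood cell score was 3.18 ± 0.67 in susceptible mice (n = 8) and 2.29 ± 0.54 in controls (n = 8) in log2 CPM, with a two-sided exact permutation p of 0.0135 and an adjusted p of 0.203 over the cell types.

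Genes of cholinergic neurons had higher estimates in susceptible mice. Chat, which makes acetylcholine, averaged 51.5 ± 23.1 CPM against 22 ± 11.7 CPM (n = 8 and 8), and the choline transporter Slc5a7 120 ± 72.6 against 50.2 ± 26.8 CPM. These 2 of 4 genes passed when adjusted over the list alone (edgeR adjusted p = 0.0253 and 0.0479) and 0 passed over all genes. That count was 0 without control replicate 4 or susceptible replicate 3 or 7, and 1 without control replicate 1, 3, 5, 7 or 8 or susceptible replicate 2, 4 or 8. It was also 0 without the libraries of low Tph2 and 0 without those that stood apart.

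Control replicate 7 held 367.5 CPM of Gabra6 and 528.5 CPM of Slc17a7, where no other control held 10 CPM of either. The cerebellar granule cell receptor subunit Gabra6 averaged 0.332 ± 0.639 CPM in susceptible mice and 46.3 ± 130 CPM in controls (n = 8 and 8), and the vesicular glutamate transporter Slc17a7 4.64 ± 2.95 against 70.8 ± 185 CPM. Over the list alone 5 of 7 cerebellum genes passed (Gabra6, Cbln3, Car8, Zic1 and Zic2), none of them over all genes, and 0 passed without control replicate 7. Of the glutamate neuron genes Slc17a7 and Neurod2 passed when adjusted over the list alone (2 genes, 0 over all genes), and 0 passed without control replicate 7 or susceptible replicate 1 or 8 or without the libraries of low Tph2.

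All 15 cholesterol synthesis genes had higher estimates in susceptible mice, with a mean log2 fold change of 0.18. Among them Dhcr7 averaged 69.4 ± 4.03 against 58.6 ± 9.48 CPM (n = 8 and 8). None (0) of the 15 passed over the list alone or over all genes. Of the genes induced by glucocorticoids, Sgk1 averaged 111 ± 50.2 against 67.4 ± 23.5 CPM and Fkbp5 27.1 ± 3.9 against 23.3 ± 3.52 CPM. The neuronal activity gene Fos averaged 26.6 ± 5.07 against 22.8 ± 6.32 CPM. In camera with a preset correlation 11 of 30 lists passed, among them cholesterol synthesis (adjusted p = 3.03e-08) and blood cells (1.13e-05). With an estimated correlation 0 passed, the lowest being blood cells (adjusted p = 0.0833 with an estimated correlation, and 0.0267 without the libraries of low Tph2), and with fry 0 passed (lowest adjusted p = 0.183). Over all 17036 genes edgeR called 0, with 722 at an unadjusted p under 0.05, where 0.05 of the genes makes 852. DESeq2 called 0 (750 at the same unadjusted level) and limma-voom 0 (919).

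The same 8 controls served for the comparison with resilient mice, so the values below are not independent of those above. Hbb-bs averaged 32.1 ± 17.8 CPM in resilient mice (n = 8) against 16 ± 5.96 CPM (n = 8), and Hba-a1 14.4 ± 11 against 6.36 ± 3.02 CPM. With Hba-a2 these made 3 of 5 blood cell genes that passed when adjusted over the list alone (edgeR adjusted p = 0.0246) and 0 over all genes, and the count was 0 without resilient replicate 3 or 5 or without the libraries that stood apart, which include both. The blood cell score was 2.99 ± 0.72 against 2.29 ± 0.54 in log2 CPM (n = 8 and 8, two-sided exact permutation p of 0.0491, adjusted p of 0.368). Zbtb16, a zinc finger gene induced by glucocorticoids, fell to 13.5 ± 5.85 CPM from 29.4 ± 12.7 CPM (log2 fold change -1.12, SE 0.31). It was 1 glucocorticoid gene that passed over the list alone (edgeR adjusted p = 0.0184), with 0 over all genes. The count was 0 without control replicate 7 and 2 without control replicate 2 or resilient replicate 6, and 0 without the libraries of low Tph2 or those that stood apart.

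No further gene of resilient mice passed over its list alone (0 genes). Tgm2 averaged 1.7 ± 0.705 against 2.34 ± 0.695 CPM (n = 8 and 8) and Fos 23.9 ± 6.24 against 22.8 ± 6.32 CPM. Of 30 lists 11 passed camera with a preset correlation, with ribosomal proteins lowest (25 of 25 estimates higher, mean log2 fold change 0.42, adjusted p = 2.32e-08). None (0) passed with an estimated correlation (lowest adjusted p = 0.435 with an estimated correlation) or with fry (0.537). At adjusted p under 0.05 edgeR called 0 genes (587 at unadjusted p under 0.05), DESeq2 0 (720) and limma-voom 0 (710).

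Susceptible and resilient mice were then compared with each other. All 12 genes of endothelial cells and pericytes had higher estimates in susceptible mice, with a mean log2 fold change of 0.26: the pericyte gene Rgs5 averaged 72 ± 11.7 against 53.2 ± 12.3 CPM (n = 8 and 8). Camera gave this list an adjusted p of 1.75e-09, an adjusted p = 0.0612 with an estimated correlation, and fry 0.482, and 0 of its genes passed over the list alone or over all genes. The hypothalamic peptides Pmch (0.358 ± 0.233 against 10.1 ± 27.8 CPM) and Hcrt (0.575 ± 0.545 against 5.03 ± 13.1 CPM) were high in few resilient libraries, and Pmch was the 1 neuropeptide that passed when adjusted over the list alone (edgeR adjusted p = 0.0361, 0 over all genes). It did not pass (0 genes) without resilient replicate 7 or without any 1 of susceptible replicates 1 to 8. Gabra6 (0.332 ± 0.639 against 14.1 ± 25.8 CPM), Cbln3, Zic1 and Car8 passed likewise over the cerebellum list alone (4 of 7, 0 over all genes), and 0 passed without resilient replicate 4 or 5 or any 1 of the 8 susceptible libraries. Without the libraries of low Tph2 neither list had a gene that passed (0), and without those that stood apart the cerebellum list had 0.

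In susceptible against resilient mice Fkbp5 averaged 27.1 ± 3.9 against 23.3 ± 1.79 CPM (n = 8 and 8). In this comparison camera with a preset correlation passed 9 of 30 lists and 0 passed with an estimated correlation or fry. Between these 2 groups edgeR called 0 genes (377 at unadjusted p under 0.05), DESeq2 0 (481) and limma-voom 0 (665).

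In the second defeat cohort the comparison asked what differed after defeat, without a division by outcome. Lmo3, which encodes a LIM-only cofactor of transcription (chromosome 6, 138362918 to 138581968), fell to 41.6 ± 1.42 CPM in defeated mice (n = 6) from 58.1 ± 6.76 CPM in controls (n = 5), a log2 fold change of -0.48 (SE 0.06, edgeR adjusted p = 0.0402). It was the 1 gene of 18849 that edgeR called. Its adjusted p was 0.00393 without control replicate 1, 0.0383 without control replicate 6 and 0.0543 to 0.201 without any other 1 library. Totals were 16.58 to 22.4 M in controls, except replicate 1 (50.88), and 35.97 to 53.72 M in defeated mice. Depth thus differed with defeat, and its effect was not tested. Without control replicate 1 edgeR called 3 genes, with 2 surrogate variables 66 and without the libraries of low Tph2 29. limma-voom called 1 gene and DESeq2 19. Counts at an unadjusted p under 0.05 were 1060 (edgeR), 1432 (limma-voom) and 1104 (DESeq2), where 0.05 of the genes makes 942.

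After defeat 11 of 13 neuronal plasticity genes had lower estimates, as had 4 of 5 glutamate neuron genes (0 passed), with Neurod2 at 3.15 ± 0.437 against 12 ± 19.3 CPM and Slc17a7 at 7.89 ± 6.97 against 35.2 ± 69.1 CPM. Control replicate 1 had the highest glutamate neuron score of its group (5.292). The kinase gene Camk2b was lower (602 ± 35.8 against 699 ± 17.4 CPM, n = 6 and 5, log2 fold change -0.22), as was the synaptic pentraxin Nptx1 (175 ± 38 against 242 ± 16.7 CPM, log2 fold change -0.47). These 2 of 13 plasticity genes passed when adjusted over the list alone (edgeR adjusted p = 0.00448 and 0.0362) and 0 over all genes. Camk2b passed without any 1 library, and the count was 1 without control replicate 1, 3, 4 or 5 or defeat replicate 1, 3 or 4. All 15 genes of oligodendrocytes and myelin had higher estimates, and Aspa, which breaks down N-acetylaspartate, passed over the list alone (43.3 ± 2.66 against 35.7 ± 3.45 CPM, edgeR adjusted p = 0.0124, 1 gene, 0 over all genes). That count was 11 without control replicate 5 and 10 without the libraries of low Tph2, where the plasticity count was 1.

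Of 13 mitochondrially encoded genes 5 fell after defeat when adjusted over the list alone, and 0 over all genes: mt-Cytb averaged 4020 ± 306 against 4820 ± 510 CPM (n = 6 and 5), mt-Nd2 2710 ± 177 against 3240 ± 411 CPM and mt-Co1 6020 ± 529 against 7240 ± 876 CPM, with mt-Nd1 and mt-Nd4. The count was 0 without control replicate 4, 5 or 6 or defeat replicate 2 or 6, 8 without control replicate 1 or without the libraries of low Tph2, and 9 without defeat replicate 4. Wdr5, a subunit of H3K4 methyltransferases that reads serotonylated H3, averaged 27.7 ± 1.03 against 31.2 ± 1.45 CPM, Fos 20.2 ± 8.02 against 19.7 ± 7.2 CPM and Fkbp5 21.9 ± 2.82 against 22.7 ± 2.01 CPM. Tph2 averaged 271 ± 169 against 238 ± 230 CPM and Slc6a4 221 ± 136 against 186 ± 179 CPM. After defeat 12 of 29 lists passed camera with a preset correlation, among them myelin (adjusted p = 2.22e-09), and 0 passed with an estimated correlation (lowest adjusted p = 0.181 with an estimated correlation) or with fry (0.143).

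In the vector cohort, the effect of stress was first asked under the empty vector. Of 15 glucocorticoid response genes 14 had higher estimates: Sgk1, a kinase gene induced by stress hormones, averaged 101 ± 52.9 CPM in stressed (n = 8) and 49.4 ± 9.64 CPM in control mice (n = 7, log2 fold change 1.04, SE 0.31), and Fkbp5, a co-chaperone of the glucocorticoid receptor, 28 ± 2.98 against 23.7 ± 2.04 CPM (0.24, SE 0.08). Tsc22d3 (112 ± 14.3 against 96.3 ± 7.59 CPM), Cdkn1a (12.4 ± 2.96 against 9.41 ± 1.86 CPM) and Arl4d (log2 fold change 0.68) made 5 of 15 genes that passed when adjusted over the list alone (edgeR adjusted p = 0.0298 to 0.0459), with 0 over all genes. The count was 0 without control replicate 3 or 5 or stress replicate 1, 3 without control replicate 2 or 6, and 2 without stress replicate 4 or 7. It was 3 without the libraries of low Tph2 and 0 without those that stood apart. Camera gave the list an adjusted p of 1.3e-08, an adjusted p = 0.112 with an estimated correlation, and fry 0.244.

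The choroid plexus transcript Ttr, which encodes a thyroxine carrier, averaged 1.51 ± 1.03 CPM in stressed and 12.8 ± 20 CPM in control mice with the empty vector (n = 8 and 7). It was the 1 choroid gene that passed over the list alone (edgeR adjusted p = 0.0076, 0 over all genes), and 0 passed without control replicate 6. Cholinergic genes had higher estimates, with Prph at 18.9 ± 6.37 against 12 ± 7.4 CPM, the vesicular acetylcholine transporter Slc18a3 at 29.7 ± 12 against 15.1 ± 12.3 CPM and Chat, whose locus on chromosome 14 contains Slc18a3, at 20.9 ± 7.21 against 12.4 ± 10.7 CPM. The peptides urocortin (Ucn, 30 ± 27.4 against 9.41 ± 6.87 CPM) and Cartpt (319 ± 257 against 110 ± 82.5 CPM), both of the neighbouring Edinger-Westphal nucleus, did likewise. Fos averaged 13 ± 2.42 against 12.3 ± 2.24 CPM and Tph2 318 ± 164 against 275 ± 218 CPM. Under the empty vector 9 of 29 lists passed camera with a preset correlation and 0 passed with an estimated correlation or fry. The edgeR count over all genes was 0 (656 at unadjusted p under 0.05, where chance gives 851), with 0 by DESeq2 (671) and 0 by limma-voom (873).

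Under the mutant vector, which carries H3.3 that cannot take up serotonin at position 5, Sgk1 also rose with stress, to 158 ± 63.6 CPM (n = 6) from 77.3 ± 23.9 CPM (n = 7, log2 fold change 1.04, SE 0.33). Errfi1, a glucocorticoid-induced inhibitor of EGF receptor signalling, rose to 37.3 ± 2.2 from 32.7 ± 2.06 CPM. These 2 of 15 genes passed when adjusted over the list alone (edgeR adjusted p = 0.0293) and 0 over all genes. The count was 0 without control replicate 1, 2, 4, 5 or 6 or stress replicate 11, 1b, 3 or 8, and 7 without stress replicate 2. It was 0 without the libraries of low Tph2. All 15 estimates of the list were higher (camera adjusted p = 7.19e-09, adjusted p = 0.119 with an estimated correlation, fry 0.231).

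Cholinergic genes had lower estimates with stress under the mutant vector: Prph averaged 9.25 ± 3.27 against 15.8 ± 4.13 CPM (n = 6 and 7). Slc5a7 averaged 31.2 ± 21.4 against 64 ± 21 CPM, Slc18a3 12.9 ± 9.57 against 27 ± 8.15 CPM and Chat 10.5 ± 9.08 against 21.4 ± 9.51 CPM. Their score was 2.68 ± 1.14 against 3.88 ± 0.4 in log2 CPM (two-sided exact permutation p of 0.00758, adjusted p of 0.114 over the cell types), and 0 of 5 passed over the list alone or over all genes. Cerebellum genes had higher estimates, with Cbln3 at 55.1 ± 125 against 5.5 ± 11 CPM and Zic2 at 25.6 ± 27.7 against 11.2 ± 3.14 CPM. Over the list alone 6 of 9 passed, and 0 over all genes, and the count was 0 without control replicate 1 or 3 or stress replicate 7 or without the libraries that stood apart. Of the glutamate neuron genes Neurod1 passed alone (22.4 ± 36.5 against 7.05 ± 4.26 CPM, 1 gene over the list alone, 0 over all genes), with 0 without control replicate 1, 3, 4, 5 or 6, stress replicate 7 or the libraries that stood apart. Pomc, the precursor of beta-endorphin, was 1 neuropeptide that passed likewise (2.53 ± 1.14 against 1.58 ± 0.332 CPM, 0 over all genes), with 0 without any 1 of control replicates 2 to 7 or stress replicate 2, 3 or 8. Tph2 averaged 182 ± 184 against 264 ± 164 CPM. Of 29 lists camera with a preset correlation passed 8 and 0 passed with an estimated correlation or fry. No gene passed in edgeR (0, with 460 at unadjusted p under 0.05), DESeq2 (0, 478) or limma-voom (0, 961).

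The interaction of both effects, the stress difference under the mutant vector minus that under the empty vector, was tested directly. All 5 cholinergic neuron genes had a lower stress difference under the mutant vector: Slc18a3 by a log2 value of -2.02 (SE 0.7), Chat by -1.77 (SE 0.68), Slc5a7 by -1.72 (SE 0.68), Isl1 by -1.45 (SE 0.69) and Prph by -1.42 (SE 0.45). The 5 passed when adjusted over the list alone (edgeR adjusted p = 0.0172 to 0.0436), 0 passed over all genes, and 4 or 5 passed when any single library was left out. Camera gave the list an adjusted p of 1.18e-11, an adjusted p = 0.034 with an estimated correlation, and fry 0.0399, and it was the 1 list of the 15 comparisons that passed all 3 tests. Its adjusted p with an estimated correlation rose above 0.05 without empty-vector control replicate 2 (0.063) or 7 (0.0505), mutant-vector control replicate 3 (0.0706) or 4 (0.051), empty-vector stress replicate 3 (0.0741), 5 (0.0767), 7 (0.0527) or 9 (0.0665), or mutant-vector stress replicate 1b (0.0985) or 11 (0.135). Fry passed in 13 of 28 such fits and gave 0.0514 to 0.113 without empty-vector control replicate 2, 3 or 7, mutant-vector control replicate 1, 2, 3, 4 or 6, empty-vector stress replicate 1, 3, 5, 7 or 11, or mutant-vector stress replicate 1b or 11. The mean over the 5 genes stayed between -2.02 and -1.47 when single libraries were left out. That adjusted p was also 0.115 without the 4 libraries of low Tph2 (mean -1.24), 0.109 with the run of accession numbers as a covariate (-1.66) and 0.603 with the numbers in the titles as a block (-1.46). Without the libraries that stood apart it was 0.04997 and fry gave 0.107. The raphe lies beside the cholinergic oculomotor nuclei, and the Edinger-Westphal peptides Ucn and Cartpt had interaction values of -2.45 and -2.14.

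The same interaction had higher values for Zic1 (2.36) and Zic2 (1.8) of the cerebellum list, which were the 2 genes that passed over that list alone (edgeR adjusted p = 0.0232, 0 over all genes), with 0 without empty-vector control replicate 2 or 3 or mutant-vector stress replicate 7. It was 0 too without the libraries of low Tph2 or those that stood apart. The clock output gene Hlf (0.87, SE 0.27) was 1 gene that passed over its list alone (edgeR adjusted p = 0.0326, 0 over all genes). That count was 0 without empty-vector control replicate 2, 3 or 6, mutant-vector control replicate 2, 4 or 5, empty-vector stress replicate 1, 5 or 7, mutant-vector stress replicate 2, 8 or 11, the libraries of low Tph2 or those that stood apart. It was 2 without empty-vector control replicate 1 or mutant-vector stress replicate 1b. Other interaction values were -1.05 (SE 0.9) for the raphe transcription factor gene Fev, -0.75 for Tph2, -0.82 for Slc6a4, -0.15 for Fkbp5 and -0.05 for Fos. For this interaction 10 of 29 lists passed camera with a preset correlation, 1 with an estimated correlation and 1 with fry. Over 17024 genes edgeR called 0 for the interaction (732 at unadjusted p under 0.05), DESeq2 0 (750) and limma-voom 0 (1275).

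Stressed mice with the mutant vector were compared with stressed mice with the empty vector, which share libraries with the comparisons above. Errfi1 was higher under the mutant vector (37.3 ± 2.2 CPM, n = 6, against 31.6 ± 3.42 CPM, n = 8, log2 fold change 0.24, SE 0.06). It was 1 of 15 glucocorticoid genes that passed over the list alone (edgeR adjusted p = 0.00458) with 0 over all genes, and the count was 2 without empty-vector stress replicate 1 and 3 without mutant-vector stress replicate 2. Shank3, a scaffold of excitatory synapses, passed over its list alone (146 ± 16.9 against 115 ± 11 CPM, edgeR adjusted p = 0.0103, 1 gene, 0 over all genes), and did not without mutant-vector stress replicate 2 (0 genes). Gad1 passed over the GABA list alone (534 ± 48 against 429 ± 52.6 CPM, edgeR adjusted p = 0.0296, 1 gene, 0 over all genes), with 0 without empty-vector stress replicate 1, 9 or 11 or mutant-vector stress replicate 1b, 2 or 3. The neurofilament gene Prph passed over the cholinergic list alone (9.25 ± 3.27 against 18.9 ± 6.37 CPM, edgeR adjusted p = 0.0169, 1 gene, 0 over all genes). That count was 0 without mutant-vector stress replicate 11 or 1b, 3 without its replicate 8 or empty-vector stress replicate 4, 4 without empty-vector stress replicate 6 or 9 or mutant-vector stress replicate 7, and 2 without mutant-vector stress replicate 2. Without the libraries of low Tph2 the counts were 0 for the glucocorticoid list, 0 for GABA neurons and 3 for cholinergic neurons, and without those that stood apart 2, 0 and 1.

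All 15 serotonin neuron genes had lower estimates under the mutant vector in stressed mice, with a mean log2 fold change of -0.49. Mutant-vector stress replicate 1b, with 3.713 CPM of Tph2, had the lowest serotonin score of its group (2.998), and without the libraries of low Tph2 the mean was -0.35. Fev averaged 9.24 ± 7.69 against 20.5 ± 13.6 CPM (n = 6 and 8) and Tph2 182 ± 184 against 318 ± 164 CPM. Slc6a4 averaged 131 ± 133 against 238 ± 121 CPM and Slc18a2 137 ± 103 against 200 ± 94.4 CPM. Camera gave an adjusted p of 9.11e-05 for this list, an adjusted p = 0.666 with an estimated correlation, and fry 0.546, and 0 genes passed over the list alone or over all genes. Slc18a3 averaged 12.9 ± 9.57 against 29.7 ± 12 CPM and Slc5a7 31.2 ± 21.4 against 66.2 ± 31.4 CPM. H3f3a, 1 of the genes for H3.3, averaged 19 ± 2.24 against 18.2 ± 1.97 CPM, while H3f3b lay between 0.128 and 0.701 CPM over all libraries of this table, so the vector product could not be followed.

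Camera with a preset correlation passed 9 of 29 lists between these groups and 0 passed with an estimated correlation or fry. edgeR called 0 genes (1017 at unadjusted p under 0.05), limma-voom 0 (1097) and DESeq2 1 (1092), which was Glrx5 (chromosome 12, 105032688 to 105042906), a mitochondrial glutaredoxin gene named here after its values were seen. Glrx5 had a DESeq2 log2 fold change of -1.76, and it was also the 1 gene that edgeR called with the numbers in the titles as a block (-2.18). Only 3 numbers were shared between these groups (correlations 0.14 to 0.44), too few to show pairs, so the main count stays 0.

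Stressed mice with the mutant vector were also compared with stressed mice with wild-type H3.3, where both vectors carry the histone. Shank3 averaged 146 ± 16.9 CPM (n = 6) against 116 ± 11.1 CPM (n = 8, log2 fold change 0.33, SE 0.09), and was 1 gene that passed over the synapse list alone (edgeR adjusted p = 0.0151, 0 over all genes), with 0 without mutant-vector replicate 2. The peptide galanin (Gal) was 1 gene that passed over the neuropeptide list alone (3.18 ± 3.88 against 1.27 ± 0.449 CPM, edgeR adjusted p = 0.023, 0 over all genes), with 0 without wild-type replicate 3 and 2 without mutant-vector replicate 11 or 1b, wild-type replicate 1 or the libraries of low Tph2. Cerebellum genes were high in mutant-vector replicate 7: Car8 averaged 89.9 ± 161 against 19.2 ± 9.91 CPM, Cbln3 55.1 ± 125 against 3.72 ± 6.85 CPM and Neurod1 22.4 ± 36.5 against 5.92 ± 2.61 CPM. Over their lists alone 8 of 9 cerebellum and 2 of 6 glutamate neuron genes passed, 0 over all genes, and 0 of either without that library.

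Of the serotonin genes of this comparison Htr1a was at 34.5 ± 8.19 against 43.8 ± 8.77 CPM (n = 6 and 8), Fev at 9.24 ± 7.69 against 17.9 ± 9.24 CPM and Tph2 at 182 ± 184 against 346 ± 163 CPM. The mean log2 fold change of the serotonin neuron list was -0.47, and -0.32 without the libraries of low Tph2, here replicate 1b of the mutant vector. Per1 (95 ± 22.8 against 69.3 ± 11.4 CPM) was 1 gene that passed over the clock and the glucocorticoid list alone (edgeR adjusted p = 0.0287 and 0.0307, 0 over all genes). Both counts were 0 without mutant-vector replicate 11, 1b or 7, wild-type replicate 2, 3 or 4 or the libraries of low Tph2. The glucocorticoid count was also 0 without mutant-vector replicate 8 and 3 without wild-type replicate 11. The clock count was 0 without wild-type replicate 11, 2 without mutant-vector replicate 2 or 8, wild-type replicate 5 or the libraries that stood apart, and 3 without wild-type replicate 9. The GABA neuron score was 8.13 ± 0.07 against 8 ± 0.08 in log2 CPM (two-sided exact permutation p of 0.013, adjusted p of 0.135). Among 29 lists, 12 passed camera with a preset correlation and 0 passed with an estimated correlation (lowest adjusted p = 0.208 with an estimated correlation) or with fry (0.454). Counts over all genes were 0 in edgeR (467 at unadjusted p under 0.05), 0 in DESeq2 (521) and 0 in limma-voom (1148).

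The vectors were compared without stress as well. Ttr fell to 1.04 ± 1.7 CPM under the mutant vector (n = 7) from 12.8 ± 20 CPM under the empty vector (n = 7, log2 fold change -3.61, SE 0.9), where empty-vector control replicate 6 held 55.04 CPM. With single libraries left out it passed at log2 fold changes of -4.98 to -2.47. It was 1 choroid plexus gene that passed over the list alone (edgeR adjusted p = 0.0032, 0 over all genes), and 2 passed without mutant-vector control replicate 4 or without both libraries that stood apart. Ucn averaged 34.2 ± 18.2 against 9.41 ± 6.87 CPM, Cartpt 352 ± 159 against 110 ± 82.5 CPM, Slc18a3 27 ± 8.15 against 15.1 ± 12.3 CPM and Chat 21.4 ± 9.51 against 12.4 ± 10.7 CPM. Tph2 averaged 264 ± 164 against 275 ± 218 CPM. Camera with a preset correlation passed 8 of 29 lists and 0 passed with an estimated correlation (lowest adjusted p = 0.14 with an estimated correlation) or fry (0.644). In unstressed mice edgeR called 0 genes (344 at unadjusted p under 0.05), DESeq2 0 (376) and limma-voom 0 (658).

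**Figure D2:**
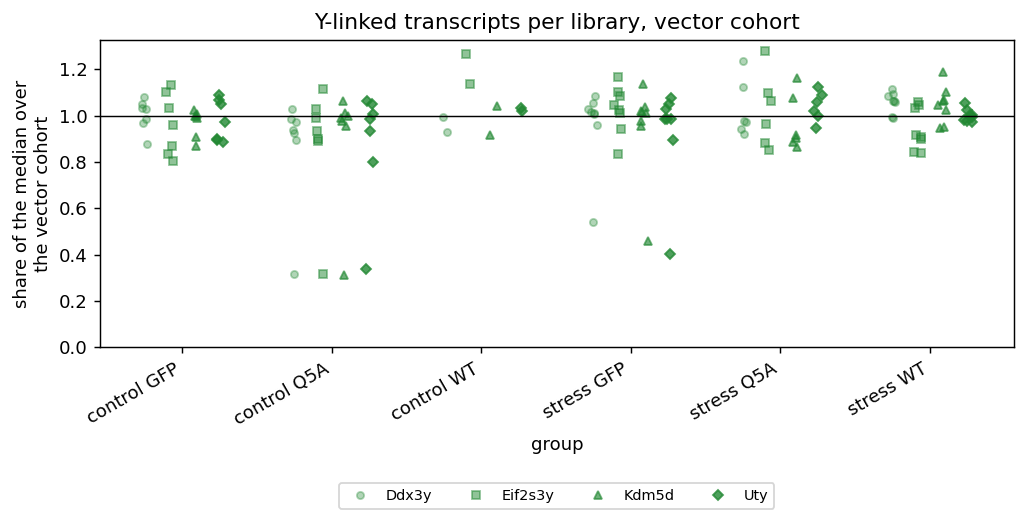
Ddx3y, Eif2s3y, Kdm5d and Uty in each library of the vector cohort, as a share of the cohort median (line at 1), by group. Replicate 4 of the mutant-vector controls lies near 0.314 for all 4 transcripts.

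Under wild-type H3.3 the stress comparison rested on 2 control libraries that differed from each other. The activity-induced receptor gene Nr4a1 (chromosome 15, 101266846 to 101274792) averaged 12.2 ± 1.96 CPM in stressed (n = 8) and 32.7 ± 23.6 CPM in control mice (n = 2, log2 fold change -1.42, SE 0.28). Arc averaged 32.6 ± 3.42 against 51.3 ± 24.3 CPM. Egr4 averaged 1.77 ± 0.554 against 6 ± 6.23 CPM and Dusp1 13 ± 1.13 against 16.6 ± 2.07 CPM, and 8 of 16 immediate early genes passed over the list alone with 0 over all genes. The glutamate neuron genes Slc17a7 (19.9 ± 25.8 against 231 ± 299 CPM), Tbr1 (1.72 ± 2.59 against 24.9 ± 33.4 CPM) and Neurod2 (4.72 ± 2.15 against 18.9 ± 22.5 CPM) passed likewise (3 of 6, 0 over all genes). Per1 (69.3 ± 11.4 against 111 ± 28.1 CPM), Stx1a (39.8 ± 6.14 against 81.1 ± 59.9 CPM) and Camk2a (226 ± 89.8 against 680 ± 748 CPM) each passed over their lists alone and not over all genes. Without control replicate 2 the count was 0 in each of these lists, and without control replicate 1 edgeR called 299 genes, 14 higher and 285 lower, with 3 clock and 7 synapse genes over their lists alone. Fos averaged 14.4 ± 3.64 against 13.6 ± 4.92 CPM. Fkbp5 averaged 30.9 ± 4.05 against 29.4 ± 3.49 CPM and Tph2 346 ± 163 against 386 ± 270 CPM. Camera with a preset correlation passed 8 of 29 lists, among them immediate early genes (adjusted p = 2.42e-07, adjusted p = 0.628 with an estimated correlation, fry 0.43). With all libraries edgeR called 0 genes (1062 at unadjusted p under 0.05), limma-voom 0 (831) and DESeq2 2 (1132), which were Nr4a1 and Psrc1.

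In the fluoxetine cohort, susceptible mice given water were compared with control mice given water. Microglial genes had higher estimates: the complement component C1qa averaged 34.7 ± 7.83 CPM in susceptible (n = 5) and 24.6 ± 2.37 CPM in control mice (n = 5, log2 fold change 0.49, SE 0.13) and C1qc 30.7 ± 8.91 against 21.7 ± 3.07 CPM. Trem2 averaged 8.53 ± 1.52 against 5.89 ± 1.2 CPM and Fcrls 12.6 ± 1.78 against 9.47 ± 1.47 CPM. Of the 12 genes, all with higher estimates, 9 passed when adjusted over the list alone (edgeR adjusted p = 0.0138 to 0.0484) and 0 over all genes. The count was 2 without susceptible replicate 3, 3 without susceptible replicate 4 and 0 without the libraries of low Tph2, and C1qa passed without any 1 library. Camera gave an adjusted p of 1.41e-06 for the list, an adjusted p = 0.604 with an estimated correlation, and fry 0.202, and the microglia score was 4.32 ± 0.28 against 3.94 ± 0.19 in log2 CPM (two-sided exact permutation p of 0.0476, adjusted p of 0.179). Other scores differed as much: cholinergic neurons had 2.41 ± 2.82 against 5.27 ± 0.87 (n = 5 and 5, exact permutation p of 0.0476, adjusted p of 0.179) and glutamate neurons 3.44 ± 0.61 against 2.5 ± 0.22 (exact permutation p of 0.0159, adjusted p of 0.119). Susceptible replicates 3 and 4, both of low Tph2, had the highest microglia scores of their group (4.645 and 4.543) and its lowest cholinergic scores (-0.75 and -0.513).

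The synaptic pentraxins Nptx2 (39 ± 15.2 against 19 ± 4.66 CPM, n = 5 and 5) and Nptx1 (212 ± 121 against 103 ± 19.1 CPM) rose in susceptible mice given water, 2 of 13 plasticity genes over the list alone (edgeR adjusted p = 0.0151) and 0 over all genes. That count was 0 without susceptible replicate 3 or 4 and 4 without control replicate 4 or 5. The metallothioneins Mt2 (44 ± 12.1 against 27.5 ± 4.85 CPM) and Mt1 (175 ± 45.4 against 120 ± 25 CPM) were 2 of 15 glucocorticoid genes that passed over the list alone (0 over all genes), with 0 without control replicate 2 or 3 or susceptible replicate 4 and 1 without susceptible replicate 2. The serotonin receptor gene Htr7 rose to 34.8 ± 1.96 from 28.3 ± 2.43 CPM (1 of its list, edgeR adjusted p = 0.0244, 0 over all genes), with 0 without control replicate 2 or 3 or susceptible replicate 3 and 2 without susceptible replicate 2 or 5. Syn2 (572 ± 112 against 452 ± 34.4 CPM) and the AMPA receptor gene Gria1 (461 ± 116 against 334 ± 58.8 CPM) were 2 synapse genes that passed over the list alone (0 over all genes), with 0 without control replicate 1, 2, 3 or 5 or susceptible replicate 3 or 4. Zic1 (37.9 ± 44.8 against 6.7 ± 3 CPM) and Zic2 (13.7 ± 10.2 against 4.89 ± 1.43 CPM) were 2 cerebellum genes that passed likewise (0 over all genes), with 0 without control replicate 1, 2 or 3 or susceptible replicate 3 or 4. Without the libraries of low Tph2 the count was 1 for serotonin receptors and 0 for each of the other lists of this paragraph.

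Tgm2 (chromosome 2, 158116402 to 158146436) averaged 12.7 ± 1.63 CPM in susceptible and 9.68 ± 2.08 CPM in control mice given water (n = 5 and 5, log2 fold change 0.39). The Y-linked Uty (15.9 ± 3.94 against 21.2 ± 2.08 CPM) and Kdm5d (33.2 ± 3.83 against 39.3 ± 3.26 CPM) were 2 genes that passed over the sex-linked list alone (0 over all genes), with 0 without control replicate 2, 3 or 4, susceptible replicate 2 or 3 or the libraries of low Tph2. Slc5a7 averaged 43.2 ± 38.3 against 184 ± 71.9 CPM, Tph2 609 ± 540 against 1070 ± 774 CPM and Slc6a4 505 ± 451 against 858 ± 599 CPM. Fos averaged 22.5 ± 5.64 against 19.7 ± 9.49 CPM and Fkbp5 35.5 ± 11.5 against 31.9 ± 3.39 CPM. The cerebellum score was 3.78 ± 0.6 against 2.99 ± 0.18 in log2 CPM (two-sided exact permutation p of 0.0159, adjusted p of 0.119). Camera with a preset correlation passed 10 of 30 lists and 0 passed with an estimated correlation or fry. edgeR called 0 of 18673 genes, with 2701 at an unadjusted p under 0.05 where chance gives 934. DESeq2 called 145 (2743), 63 higher and 82 lower, and limma-voom 1 (2976), the predicted gene Gm48267. Without control replicate 4 edgeR called 2 genes.

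Fluoxetine was then compared with water in control mice, which share the 5 water controls. Tgm2 rose to 14.7 ± 1.26 CPM (n = 5) from 9.68 ± 2.08 CPM (n = 5), a log2 fold change of 0.6 (SE 0.13, edgeR adjusted p = 0.0023 over the serotonylation and H3K4 methylation list alone, 1 gene, 0 over all genes). Htr7 rose to 36.7 ± 4.36 from 28.3 ± 2.43 CPM (edgeR adjusted p = 0.00292 over the serotonin receptor list alone, 1 gene, 0 over all genes), with 2 genes passing without fluoxetine replicate 3. Both genes and the microglial Fcrls passed without any 1 library. Fcrls (13.8 ± 0.724 against 9.47 ± 1.47 CPM), C1qa (31.7 ± 3.53 against 24.6 ± 2.37 CPM), C1qb (32 ± 3.81 against 23.4 ± 4.13 CPM) and C1qc (29.9 ± 3.98 against 21.7 ± 3.07 CPM) were 4 of 12 microglia genes that passed over the list alone (0 over all genes). The count was 1 without fluoxetine replicate 1, 2 or 5 or water replicate 2, 3 or 4, and 2 without fluoxetine replicate 3.

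Cholesterol synthesis genes had lower estimates with fluoxetine in control mice: Insig1 averaged 143 ± 16.2 against 190 ± 15.5 CPM (n = 5 and 5) and Hmgcs1 289 ± 33.5 against 367 ± 31.7 CPM. All 16 estimates were lower, and 6 genes passed over the list alone, among them these and Sqle and Dhcr7 (edgeR adjusted p = 0.0182 to 0.0349, 0 over all genes). The count was 0 without fluoxetine replicate 3 or water replicate 3, 3 without fluoxetine replicate 1 or 5 and 2 without water replicate 2 or the libraries of low Tph2. Camera gave an adjusted p of 5.77e-09 for this list, an adjusted p = 0.292 with an estimated correlation, and fry 0.159. The astrocyte genes Aldh1l1 (96.4 ± 3.89 against 70.7 ± 10.8 CPM) and Gjb6 (83.6 ± 5.46 against 60.2 ± 8.62 CPM) were 2 genes that passed over the list alone (0 over all genes). That count was 0 without fluoxetine replicate 1 or 2 or water replicate 2, 3 or 4, 1 without fluoxetine replicate 3 or 5 or the libraries of low Tph2, and 7 without water replicate 5. The astrocyte score was 7.86 ± 0.1 against 7.51 ± 0.25 in log2 CPM (two-sided exact permutation p of 0.0317, adjusted p of 0.218).

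Serotonin neuron genes all had lower estimates in fluoxetine-treated control mice (15 of 15, mean log2 fold change -1.55): Tph2 averaged 172 ± 259 against 1070 ± 774 CPM (n = 5 and 5). Slc6a4 averaged 167 ± 259 against 858 ± 599 CPM and Slc18a2 122 ± 166 against 599 ± 410 CPM. None of them passed over the list alone or over all genes (0), and 3 of the 5 fluoxetine libraries held less than 0.1 of the cohort's median Tph2. Without the 6 libraries of low Tph2, which leaves 2 of these 5, Htr7 still passed over its list alone (1 gene), while Tgm2 and the microglia genes did not (0 genes each) and 2 cholesterol genes did. The mean of the serotonin list was then -0.8. Fos averaged 10.8 ± 4.07 against 19.7 ± 9.49 CPM.

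The glutamate neuron genes Slc17a7 (30.4 ± 60.5 against 0.955 ± 0.603 CPM, n = 5 and 5), Neurod2 (7.34 ± 5.84 against 2.51 ± 1.7 CPM), Tbr1, Neurod1 and Slc17a8 passed over the list alone in the same comparison (5 genes, 0 over all genes). Their count was 0 without fluoxetine replicate 2 or water replicate 2 and 3 without water replicate 3. Nptx2 (36.7 ± 8.24 against 19 ± 4.66 CPM), Mt2 (41.9 ± 8.78 against 27.5 ± 4.85 CPM), the interferon gene Ifit3 (10.4 ± 2.65 against 6.54 ± 1.16 CPM) and the clock gene Tef (335 ± 15.9 against 256 ± 15.7 CPM) were each 1 gene that passed over its list alone (0 over all genes). The plasticity count, of Nptx2, was 0 without fluoxetine replicate 2, 3, 4 or 5 or water replicate 1, 2 or 3, 3 without water replicate 4 and 5 without water replicate 5. The glucocorticoid count, of Mt2, was 0 without fluoxetine replicate 1, 2 or 3 or water replicate 2, 3 or 4 and 2 without fluoxetine replicate 4 or water replicate 5. The interferon count was 0 without fluoxetine replicate 1 or 2 or water replicate 1, 2 or 3 and 3 without water replicate 5. The clock count was 0 without fluoxetine replicate 1, 2, 3 or 5 or any 1 of water replicates 1 to 5, and 3 without fluoxetine replicate 4. Without the libraries of low Tph2 the plasticity count was 1 and the others of this paragraph 0. With fluoxetine 14 of 30 lists passed camera with a preset correlation and 0 passed with an estimated correlation or fry. In this pair of groups edgeR called 0 genes (1557 at unadjusted p under 0.05), DESeq2 0 (1688) and limma-voom 0 (4017), and edgeR called 1 gene without fluoxetine replicate 3.

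**Figure D3:**
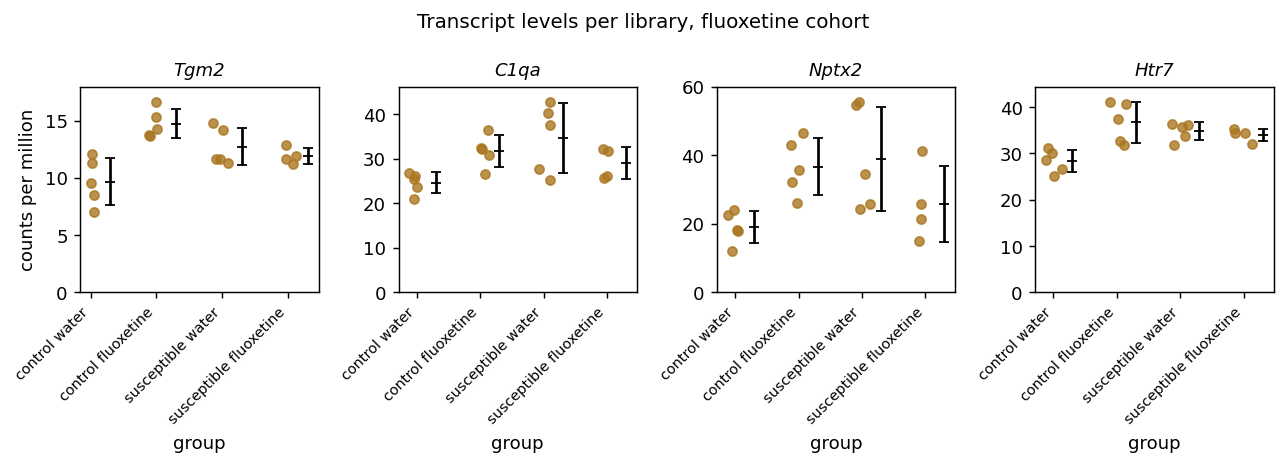
Tgm2, C1qa, Nptx2 and Htr7 in CPM in each library of the 4 groups of the fluoxetine cohort, with mean ± SD beside the points. Tgm2 averaged 9.68 CPM in water controls and 14.7 CPM in fluoxetine controls.

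In susceptible mice, fluoxetine was compared with water. The gene of gastrin-releasing peptide, Grp (chromosome 18, 65872820 to 65886579), fell to 2.04 ± 0.733 CPM (n = 4) from 5.91 ± 1.63 CPM (n = 5, log2 fold change -1.51, SE 0.35) and passed over the neuropeptide list alone without any 1 library. Pomc averaged 1.33 ± 0.319 against 3.95 ± 4.16 CPM, and these 2 neuropeptides passed over the list alone with 0 over all genes. The count was 1 without fluoxetine replicate 1, 2, 3 or 4 or water replicate 2. The microglia gene Trem2 averaged 5.64 ± 1.13 against 8.53 ± 1.52 CPM. Aif1 averaged 2.27 ± 0.229 against 3.81 ± 1.71 CPM and the fractalkine receptor Cx3cr1 27.5 ± 4.57 against 36.2 ± 7.41 CPM, and 3 of 12 passed over the list alone (0 over all genes). That count was 0 without fluoxetine replicate 1 or 4 or water replicate 3, 1 without fluoxetine replicate 2 or water replicate 4, and 6 without water replicate 1. The immediate early gene Junb fell to 15.2 ± 3.22 from 25.7 ± 4.09 CPM (1 gene over the list alone, 0 over all genes), with 0 without fluoxetine replicate 2, 3 or 4 or any 1 of water replicates 2 to 5. Zic1 (6.24 ± 0.699 against 37.9 ± 44.8 CPM) and Zic2 were 2 cerebellum genes that passed likewise (0 over all genes), with 0 without any 1 fluoxetine library or water replicate 3 or 4. Without the libraries of low Tph2 the counts were 3 for neuropeptides and 0 for the other lists of this paragraph.

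Other genes of fluoxetine-treated susceptible mice did not pass. Fos averaged 12.1 ± 4.34 against 22.5 ± 5.64 CPM (n = 4 and 5). Tph2 averaged 690 ± 754 against 609 ± 540 CPM and Fkbp5 43.8 ± 10.9 against 35.5 ± 11.5 CPM. Camera with a preset correlation passed 6 of 30 lists, among them ribosomal proteins (26 of 26 estimates lower, adjusted p = 4.41e-08), and 0 passed with an estimated correlation (0.667) or fry (0.661). With fluoxetine in susceptible mice edgeR called 0 genes (1465 at unadjusted p under 0.05), limma-voom 0 (2215) and DESeq2 1 (1486), Creg2, with a log2 fold change of 0.24.

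The fluoxetine effect in susceptible mice minus that in controls was tested as an interaction. All 12 microglia genes had lower values in susceptible mice, and 10 passed over the list alone (edgeR adjusted p = 0.00877 to 0.0318, 0 over all genes): Fcrls had -0.73 (SE 0.19), Trem2 -0.86 (SE 0.25), Aif1 -1.16 (SE 0.34), Cx3cr1 -0.63 (SE 0.19), Tmem119 -0.77, C1qa -0.63 and C1qc -0.7, and these 7 passed without any 1 library. The interferon-induced Ifit1 (-0.81, SE 0.23) and Ifit3 (-0.99, SE 0.27) passed over their list alone (2 genes, 0 over all genes), as did the serotonin receptor genes Htr1d (2.19, SE 0.59) and Htr7 (-0.4, SE 0.12), again without any 1 library. Of the cerebellum list 5 genes passed (0 over all genes), among them Zic2 (-2.68), Zic1 (-4.18) and Neurod1 (-1.47), and 3 without control fluoxetine replicate 2. Tgm2 had -0.69 (SE 0.19, edgeR adjusted p = 0.0222 over its list alone, 1 gene, 0 over all genes), and did not pass (0 genes) without control fluoxetine replicate 2, susceptible fluoxetine replicate 1 or 2 or susceptible water replicate 3 or 4. Without the 6 libraries of low Tph2 the counts over the list alone were 0 for microglia, 0 for cerebellum, 0 for interferon, 0 for the list of Tgm2 and 1 for serotonin receptors.

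Further genes passed over their lists alone for this interaction, and 0 over all genes: 3 of plasticity (Nptx2 at -1.54, SE 0.42, Nptx1 at -1.42 and Bdnf at -0.71), 4 of astrocytes (Agt at -0.86, Gfap at -2.09, Slc1a3 at -0.9 and Aldh1l1 at -0.55), 1 of synapses (Gria1 at -0.73, SE 0.21) and 1 of glutamate neurons (Neurod1). Without the libraries of low Tph2 each of these counts was 0. The plasticity count was 0 without susceptible fluoxetine replicate 1 or 2 or susceptible water replicate 4, 1 without susceptible fluoxetine replicate 3 or control water replicate 2, and 5 without control water replicate 5 or susceptible water replicate 1. The astrocyte count was 0 without replicate 1 or 2 of either fluoxetine group, control water replicate 2 or 3 or susceptible water replicate 3 or 4, 1 without control water replicate 1, 2 without control fluoxetine replicate 5 and 7 without control water replicate 5. The synapse count was 0 without control fluoxetine replicate 1, 3 or 5, control water replicate 1, 2 or 3, susceptible fluoxetine replicate 1, 2 or 3 or susceptible water replicate 3 or 4, 2 without susceptible fluoxetine replicate 4 or susceptible water replicate 1 or 5, and 3 without susceptible water replicate 2. The glutamate count was 0 without susceptible fluoxetine replicate 1 or 3, 2 without control fluoxetine replicate 4 or 5 or susceptible water replicate 1 or 5, and 3 to 6 without susceptible fluoxetine replicate 2 (3) or 4 (5), control water replicate 1 (4) or control fluoxetine replicate 3 (6).

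Other interaction values in this cohort were 2.82 for Tph2, 2.85 for Slc6a4, 0.21 for Fkbp5 and -0.04 for Fos. Of the 30 lists, 12 passed camera with a preset correlation, with microglia at an adjusted p of 4.79e-08, an adjusted p = 0.423 with an estimated correlation, and fry 0.0806. For this interaction edgeR called 0 genes (2285 at unadjusted p under 0.05), limma-voom 0 (3028) and DESeq2 63 (2388), 37 higher and 26 lower.

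Sets of 200 genes taken from a stress comparison were scored in libraries that had not chosen them, to ask whether a stress difference recurred elsewhere. Of the susceptible set 37 rising and 134 falling genes were found in the second cohort. The vector cohort held 31 and 141, the fluoxetine 37 and 143. The Y-linked Ddx3y averaged 58.3 ± 10.5 CPM in the first cohort (n = 24) and 0.035 ± 0.0518 CPM in the second (n = 11). The first thus read as male, the second as female. The susceptible set of the first cohort differed by 0.01 between defeated and control mice of the second cohort (n = 6 and 5, two-sided exact permutation p of 0.918). It differed by 0.24 with stress under the empty vector (n = 8 and 7, permutation p 0.186). Between mutant and empty vector in stressed mice it differed by -0.34 (n = 6 and 8, permutation p 0.158). In the fluoxetine cohort it differed by -0.63 between susceptible and control mice given water (n = 5 and 5, permutation p 0.175). Between susceptible mice given fluoxetine and water it differed by 0.55 (n = 4 and 5, permutation p 0.183). The empty-vector stress set differed by -0.08 between stressed mice with the mutant and the wild-type vector (n = 6 and 8, permutation p 0.382). It differed by 0.02 with stress under the mutant vector (n = 6 and 7, permutation p 0.875). The set of susceptible mice given water differed by -0.21 between susceptible and control mice given fluoxetine (n = 4 and 5, permutation p 0.151). The lowest adjusted p over the 8 tests was 0.298.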

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

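Of the tests in this part, those of dissection and of groups for the serotonin transcripts, of GC content, gene length and group for the first component, and those for the Y-linked transcripts were chosen only after the result was seen. Values are given where a library lay far from the others of its group by Dixon's test, which chance does for about 1 in 20 groups. There were 54 such values among 388 group measures, where chance gives 19.

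The transcripts of serotonin neurons spread widely within most groups, with Tph2 over 100-fold apart in 9 of 15 groups and under 10-fold in 3. Total counts did not account for this, as the strongest correlation of the serotonin score with them in any cohort was 0.39 in size. The groups held at most 18.5% of the variance of the score in any cohort. Tph2, Slc6a4, Fev, Slc18a2 and Lmx1b moved together within groups, with a lowest cohort median correlation of 0.94, so different amounts of raphe in the dissected pieces may be the source. A difference in the number or state of serotonin neurons between mice was not tested and stays open.

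The first component of the first defeat cohort held 42.8% of the variance. Lanes held 7.38% and groups 5.73% of its variance between libraries, which argues against both as its main source. Across genes, its loading had a Spearman correlation of 0.38 with GC content, of -0.43 with gene length and of -0.5 with transcript length, and genes are not independent replicates. A technical difference in RNA or library quality is a candidate source, as counts over whole gene bodies take up intron reads. The tested values do not tell GC content, gene length and transcript length apart.

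Mutant-vector control replicate 4 had low Y-linked transcripts (Ddx3y 27.73 CPM, Uty 5.389 CPM). Female RNA would raise X-linked genes that escape inactivation, but Kdm6a was 23.5 CPM (others at least 23.6 without empty-vector stress replicate 1 at 12.8). Over Kdm6a, Kdm5c, Eif2s3x and Ddx3x the mean log2 of the level over the median of others was -0.02 (SD of others 0.078), where levels of the second cohort, from another table, gave 0.3. This argues against female RNA. The shares of the median differed by 0.023 over Ddx3y, Eif2s3y, Kdm5d and Uty, so RNA without a Y and with a single X chromosome may be the source, which stays open. Its Pcsk1n was 1 times the median, which argues against the RNA difference of empty-vector stress replicate 1. No other explanation was tested for this library.

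The cholinergic list had a mean interaction of -1.67 between vector and stress. Its adjusted p with an estimated correlation was 0.034, but 0.115 without libraries of low Tph2 and 0.603 with the numbers in the titles as a block, and it passed in 18 of 28 fits that left out 1 library, so this result stays open.

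Total counts set 3 libraries apart: control replicate 6 of the first cohort (40.56 M), control replicate 1 of the second (50.88) and empty-vector control replicate 5 (71.3). Genes with reads did so for control replicate 2 (28197) and susceptible replicate 6 (20459) of the first cohort, control replicate 1 of the second (28087) and empty-vector stress replicate 1 (16979). On the first component control replicate 1 (43.47) and defeat replicate 6 (25.68) of the second cohort and susceptible fluoxetine replicate 1 (53.04) lay apart, and on the second component control replicate 5 of the second cohort (35.96) and control fluoxetine replicate 3 (24.34).

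Defeat replicate 6 of the second cohort was low in log2 CPM of Tph2 (1.02), Slc6a4 (0.17), Fev (0.62), Slc18a2 (4.22) and Fkbp5 (4.14), and mutant-vector control replicate 7 in Tph2 (3.31), Slc6a4 (2.69) and Slc18a2 (3.89). Fos lay apart in susceptible replicate 1 (4.09) and resilient replicate 3 (3.63) of the first cohort and wild-type stress replicate 4 (4.56), and Fkbp5 in empty-vector control replicate 2 (4.36). Ddx3y lay apart in control replicate 8 of the first cohort (42.53 CPM), empty-vector stress replicate 1 (47.8) and water control replicate 1 (84.56), and Uty in the latter 2 (6.438 and 17.46 CPM).

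Cell type scores in mean log2 CPM lay apart as follows. The serotonin score was 2.78 in defeat replicate 6 of the second cohort and 3.1 in mutant-vector control replicate 7. Control replicate 7 of the first cohort had a glutamate score of 5.36, a cerebellum score of 8.89 and a score of 3.3 for oligodendrocyte precursors. The dopamine and noradrenaline score was 5.04 in mutant-vector stress replicate 7 and 4.42 in control fluoxetine replicate 4. The cholinergic score was 1.66 in control replicate 1 and -0.08 in defeat replicate 6 of the second cohort and 3.75 in water control replicate 4. Cerebellum scores were 3.98 in defeat replicate 6, 5.24 in mutant-vector control replicate 2, 4.56 in wild-type stress replicate 9 and 5.09 in control fluoxetine replicate 2.

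Myelin scored 6.72 in control fluoxetine replicate 3, oligodendrocyte precursors 4.66 in mutant-vector stress replicate 3, microglia 5.06 in empty-vector control replicate 1 and 6.08 in mutant-vector control replicate 3, endothelium 4.76 in mutant-vector stress replicate 11 and ependyma 1.16 in wild-type stress replicate 11. Meninges scored 3.52 in control replicate 1 of the second cohort, 3.14 in water control replicate 4 and 3.91 in control fluoxetine replicate 2.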

How the results depend on the processing

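The fits without libraries of low Tph2 or without libraries that stood apart, those with the serotonin score as a covariate and the list tests under alternatives were chosen after seeing the data. The cause was not tested for the changes below unless stated.

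With DESeq2 the counts of genes were 19 for defeat in the second cohort (1 with edgeR), 2 for stress under wild-type H3.3, 1 for the mutant against the empty vector in stressed mice, 145 for susceptible against control mice given water, 1 for fluoxetine in susceptible mice and 63 for the fluoxetine interaction, each 0 with edgeR. limma-voom called 1 gene for susceptible against control mice given water. With 2 surrogate variables edgeR called 66 genes for defeat in the second cohort and 1 for fluoxetine in susceptible mice (Htr1d, 0.95). For defeat in the second cohort it called 2 with the serotonin score as a covariate and 29 without libraries of low Tph2. Without libraries that stood apart it called 5 genes for stress under wild-type H3.3, and with the run of accessions 1 for the mutant against the empty vector in stressed mice.

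With the numbers in the titles as a block, defeat in the second cohort gave 0 genes (Lmo3 -0.48, adjusted p 0.094) and the mutant against the empty vector in stressed mice gave 1, Glrx5 (-2.18). In the block the cholinergic interaction averaged -1.46 and did not pass (adjusted p 0.603 with an estimated correlation).

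Leaving out single libraries gave 0 to 3 genes for defeat in the second cohort, 0 to 299 for stress under wild-type H3.3, where a single control remained and was assumed to vary like the other groups, 0 to 2 for susceptible against control mice given water and 0 to 1 for fluoxetine in control mice. Lmo3 ranged from -0.51 to -0.4 and passed in 2 of 11 such fits. The cholinergic interaction ranged from -2.02 to -1.47 and passed in 18 of 28, and it did not pass without low Tph2 (-1.24) or with the run of accessions (-1.66), nor in the block.

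The susceptible set in the second cohort changed sign with 50 genes (-0.13), without low Tph2 (-0.01) and between -0.13 and 0.12 when single libraries were left out. The empty-vector stress set in mutant-vector mice changed sign with 50 genes (-0.12), with 1000 genes (-0.05) and without low Tph2 (-0.05). Of 442 list tests camera passed 149, 133 without low Tph2 and 137 without libraries that stood apart, with an estimated correlation 1 in each, and with fry 1, 0 and 0. The list that passed with an estimated correlation without low Tph2 was blood cells in susceptible against control mice (adjusted p 0.0267), in place of the cholinergic interaction.

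Of 2374 values of named genes under these alternatives 2229 kept within the spread or on their side of the threshold, 130 moved, 14 came to pass, 1 ceased to pass and 0 changed sign past the threshold.

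Random splits of the same libraries tested whether chance can be excluded. The 1 gene for defeat in the second cohort was reached by 1 of 100 splits, the real one (highest other 0). Over 14 comparisons, and with Lmo3 passing in 2 of 11 fits without 1 library, this does not exclude chance. In the same splits 28 of 100 gave as many genes at an unadjusted p under 0.05 (1060 in the real one, 1800 in the highest other). Each other real count was 0, which any split reaches (100 of 100, or 50 of 50 in the vector cohort), so these counts could not test chance. At an unadjusted p under 0.05 as many genes were reached by 4 of 100 splits for the fluoxetine interaction (2285 genes, highest other 3362), 6 for fluoxetine in control mice (1557, 2609), 11 for susceptible against control mice given water (2701, 4591), 25 to 61 for the others of 100 and 18 to 36 of 50 in the vector cohort. The highest other counts were 1 for susceptible and 582 for resilient against control mice, 6932 for susceptible against resilient mice, 617 for the vector interaction, 1167 for susceptible against control mice given water, 375 for fluoxetine in susceptible and 3 in control mice, and 124 for the fluoxetine interaction. In the vector cohort they were 3 for the mutant against the empty vector in stressed mice and 0 for the others. The splits with many genes point to a structure of the samples outside the groups. The real split of the mutant and empty vectors in stressed mice parted 3 shared numbers, and 12 other splits that parted as many gave 0 genes.

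Totals fell to 8.7 M in the fluoxetine cohort. Simulated 1.5-fold changes were recovered in 47.8% of genes in the first cohort, whose coefficient of variation was 0.301 against 0.2 in the fluoxetine cohort, and no test tied recovery to depth.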

Other observations

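H3f3a, which encodes H3.3, lay between 13.1 and 21.9 CPM in the vector cohort and H3f3b between 0.128 and 0.701 CPM, while H3f3b averaged 123 ± 8.86 CPM in susceptible mice given fluoxetine. Xist, the transcript of the inactive X chromosome, was 472 to 676 CPM in the second cohort, a female pattern.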
